A study of Mus musculus with 4 samples.

How the data were processed

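RNA was measured on 4 Affymetrix mouse gene arrays. Per the labels, each array held biotin-labelled total RNA of primary lung fibroblasts, cells grown out of collagenase-digested lung tissue of young mice and kept in serum-containing medium. The growth protocol speaks of myofibroblasts and of a purity check by immunofluorescence. 2 samples, A and B, came from a line with the oncogenic KrasD12 allele, and 2 samples, also A and B, came from a wild-type (WT) line. No treatment was applied. The titles give 1 line number per genotype, so genotype and line cannot be told apart, and nothing says whether A and B are separate cultures. The p-values of single genes therefore measure only the spread between samples A and B of a line, which may be technical. Those of gene lists at a preset correlation and of chromosomes rest on the scatter between genes. They treat genes as nearly independent and do not measure differences between lines or animals.

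The deposited values are log2 expression values, 1 per row of the array and sample, read from the values themselves, which run from 2.28 to 14.95. The submitters' processing notes name the Transcriptome Analysis Console. Its version, the background correction and the normalization are not given in the sources used here. The deposited columns had medians of 6.24 and 6.26 in KrasD12 and 5.90 and 5.91 in WT. Sorted values of A and B differed on average by 0.0237 in KrasD12 and 0.00856 in WT, while those of samples from different groups differed by 0.268 to 0.28, so the 4 columns did not share 1 distribution. Whether the groups were scaled separately stays unknown.

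The deposited file holds 28944 rows. The platform annotation pairs 21789 of them with exactly 1 gene symbol, 1621 with several and 5534 with none. Of the rows with 1 symbol, 21698 matched the mouse gene table of assembly GRCm38.p6, which was used for current names, chromosomes and gene order only, since the probe table names no build. Rows with several symbols or none were kept out of the gene tests. For the 999 genes with more than 1 row, the row with the highest mean over the 4 samples stood for the gene, which left 19938 genes. The dim level was the 95th percentile of the means of 1210 rows of olfactory and vomeronasal receptors, 5.15 on the log2 scale, and 13824 genes lay above it. Differences of genes with 1 group below that level are compressed. For arrays, their number limits the precision: 2 samples per group leave 2 residual degrees of freedom.

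Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and also with an added size of at least 2-fold (log2 difference of 1). Every difference is KrasD12 minus WT on the deposited values unless another scaling is named, and for genes called on both scalings the quantile value is given too where it differs over 1.5 times. 33 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera compares the genes of a list with all other genes. With an estimated correlation it rests on the 2 residual degrees of freedom, so a call lost there decides little about a list. Chromosomes were tested on genes above the dim level by the difference of a chromosome's median from that of the other genes, with 10000 permutations of genes over chromosomes. Tables were handled with data.table (1.17.8), pandas 2.3.3 and Python 3.11.15, and plots were drawn with matplotlib 3.10.9. Named genes are the 12 largest rises and 12 largest falls among called genes, leaving out predicted genes and genes whose higher group mean lies under the dim level, a fixed set of Ras, fibroblast, senescence and sex-linked genes, and of every list up to 4 called members with the largest differences, or, where under 2 were called, the 2 largest. This rule gave 152 genes, and other members of the lists are named as further examples chosen after their values were seen. Listed genes without a row in the values used are not analysed here.

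The groups, the tests, the lists, the rule for named genes and a set of alternatives were fixed before the data were examined. These alternatives were the replicate letter as a block, quantile normalization of the 4 columns, centring each column on its median, a filter on dim genes, eBayes with a trend or robust, the mean of a gene's rows, every row, each array left out in turn, the statistic without shrinkage, unadjusted p-values, limma's treat, an estimated correlation in camera, limma's fry, and for chromosomes no filter, quantile normalization and means. Added after seeing the data were cyclic loess normalization, an estimated correlation together with quantile normalization, and the requirement that a gene be called in the same direction on the deposited values and after quantile normalization. Because the deposited columns of the 2 groups lie apart, a gene is said to have risen or fallen only where it meets that last requirement. 6757 genes met it, and 6658 of these were also called in the same direction after cyclic loess.

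The steps were tested on simulated data. For 19938 genes in 4 simulated arrays without a shift between groups, the limma fit recovered 77% of genes changed 2-fold and 97% of those changed 4-fold and called 2 unchanged genes. With the deposited shift added, it recovered 98% and 100% and called 10478 unchanged genes (53.1%), 2 of them at the 2-fold size. Quantile normalization of those values brought the recovery to 77% and 97% and the unchanged genes called to 1. This return was fixed by construction, since the shift kept the rank order within each array. Only 200 genes were changed, as many up as down, so the simulation does not show which scaling suits the real arrays. The lists and chromosomes were simulated without that shift and with noise drawn independently for each gene. There 0 unchanged lists and 0 unchanged chromosomes were called. A list of 26 genes lowered by 0.5 on the log2 scale and a chromosome shifted by 0.1 were called.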

Results

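Gene expression was measured in 4 samples of cultured mouse lung fibroblasts, 2 of a line carrying the oncogenic KrasD12 allele and 2 of a wild-type line. The design poses 1 question: which transcripts differ between KrasD12 and WT lung fibroblasts. Across 19938 genes, Pearson's r was 0.997 between the KrasD12 samples, 0.998 between the WT samples and 0.972 to 0.974 between groups. The SD of the difference between A and B was 0.159 on the log2 scale in KrasD12 and 0.146 in WT, against 0.479 to 0.499 for pairs from different groups. Genes are not independent replicates, and these correlations describe the samples only.

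The largest measured rise between KrasD12 and WT fibroblasts was that of Slc14a1 and the largest measured fall that of Mgp. Slc14a1, a urea transporter gene, rose by 5.87 ± 0.07 on the log2 scale (limma's moderated SE, as after every ± below, n = 2 per group, limma adjusted p = 2.02e-05). It was followed by Frzb, a secreted WNT antagonist (4.61 ± 0.09), Trim12a (3.77 ± 0.11) and AI593442 (3.73 ± 0.09). Cdh4, a cadherin, rose by 3.56, Lrrn1 by 3.51, Gap43, a growth-cone protein, by 3.46 and the transporter gene Abca8a by 3.40. Nexmif, the kainate receptor gene Grik1, Cbln2 and the WNT antagonist Dkk2 rose by 3.21, 2.90, 2.82 and 2.80. Mgp, an inhibitor of matrix calcification, stood at -4.50 ± 0.07 (adjusted p = 5.08e-05), from a mean of 10.2 in WT to 5.68 in KrasD12. AI506816 (-4.34), Ifi202b (-4.14) and Eng (-3.67), a co-receptor of the TGF-beta family, came next. Usp17ld (-3.40), the vasopressin receptor gene Avpr1a (-3.26), Gdpd2 (-3.25), Fndc1 (-3.14) and Elobl (-3.12) fell as well. Tmem176b, Prss35 and Gas6, a ligand of the TAM receptor kinases, fell by 3.03, 3.01 and 2.90. All 24 genes were called on the deposited values and after quantile normalization, which moved their differences by at most 0.34. The WT mean of 6 of these rises and the KrasD12 mean of 7 of the falls lay below the dim level, AI506816 (4.21) and Ifi202b (3.58) among them. Background compresses such differences, so the 7 falls may be underestimated. For the 6 rises the deposited shift of dim genes acts the other way: Trim12a rose by 3.46 after quantile normalization. The sizes are therefore uncertain and their order is not fixed.

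On the deposited values, limma called 12372 of 19938 genes, 9991 higher and 2381 lower in KrasD12 (80.8% and 19.2%). Of these, 985 differed at least 2-fold, 728 higher and 257 lower. After quantile normalization the same test called 9346 genes, 4485 higher and 4861 lower (48.0% and 52.0%), and 688 at 2-fold, 249 higher and 439 lower. Centring the columns gave 3574 higher and 6657 lower. The requirement of a call in the same direction on both scalings left 4459 genes that rose and 2298 that fell (66% and 34%). Of these, 246 and 255 differed at least 2-fold on both. It thus kept 4459 of the 4485 quantile rises but only 2298 of the 4861 quantile falls, since most deposited values lie higher in KrasD12. Numbers of list members that rose and fell below are to be read against this split of 66% and 34%. The split covers all genes, dim ones included, and was not counted among genes of like mean. For lists of bright genes it is therefore only a rough guide. The median difference of all genes was 0.26 on the deposited values and 0.00 (-0.00375) after quantile normalization, and that of the olfactory and vomeronasal receptor rows was 0.33 and 0.01. Among genes with a mean above 10 it was -0.10 (-0.095) on the deposited values. Deposited medians of gene lists and single differences below are to be read against the shift of genes of like mean. That shift ran from 0.39 at means of 5 to 6 down to -0.15 (-0.145) at means of 11 to 12. Counts of list members are on the deposited values first. With KrasD12 A left out 5783 genes were called and with KrasD12 B left out 3887. With WT A or WT B left out limma called 0 genes, with 9846 and 10022 at an unadjusted p under 0.05 and smallest adjusted p of 0.0552 and 0.053.

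**Figure D1:**
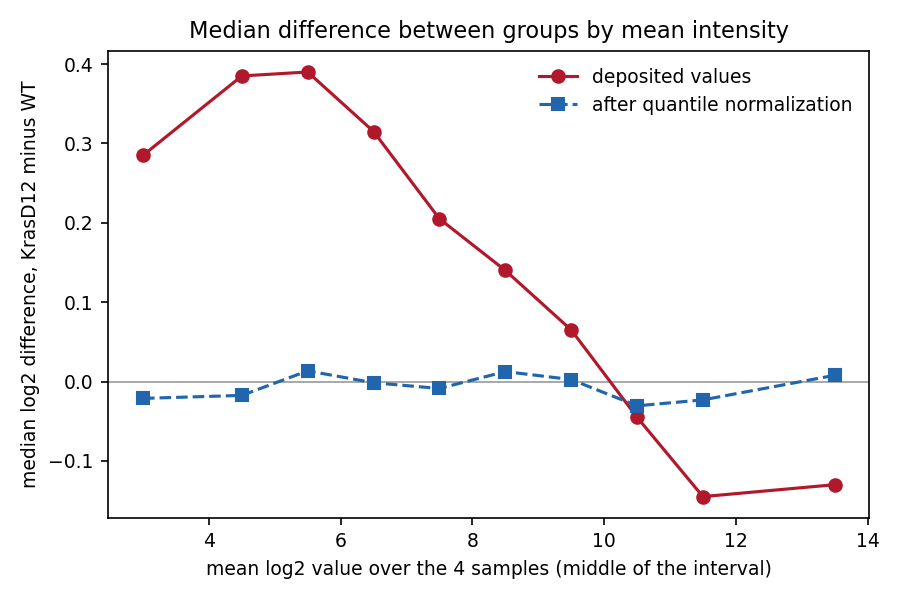
Median log2 difference between KrasD12 and WT (vertical axis) of genes grouped by their mean log2 value over the 4 samples (horizontal axis, middle of each interval), on the deposited values (circles) and after quantile normalization (squares). The deposited medians run from 0.39 among genes with means of 5 to 6 down to -0.15 (-0.145) among those with means of 11 to 12.

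More transcripts induced by the RAS-MAPK cascade rose than fell in KrasD12. Of the 33 feedback and target genes measured, 17 rose, 3 fell and 13 were not called on both scalings. Etv1, Etv5 and Etv4, ETS-family transcription factors, rose by 2.76 ± 0.08, 1.69 ± 0.07 and 1.02. Among the feedback inhibitors, Dusp6 and Dusp4, phosphatases of MAP kinases, rose by 1.70 and 1.33, Spred1 by 1.20, Spred2 by 0.97, and Spry1 and Spry2 by 0.72 each. Hmga2, a chromatin protein, rose by 1.35 and Fosb by 1.28. The members that fell were the EGF-receptor ligand gene Ereg (-1.03), Ier3 (-0.36) and Emp1 (-0.35), while Fos (-0.04), Egr1 (0.22) and Myc (0.07) did not pass on both scalings. The list median was 0.52 on the deposited values and 0.23 after quantile normalization, above 99.9% of random lists matched on mean expression. Matched random lists, here and below, are drawn gene by gene, so such comparisons treat genes as nearly independent. Camera gave an adjusted p of 0.0673 on the deposited values and 0.0145 after quantile normalization, and that call was lost at adjusted p = 0.689 with an estimated correlation. On the deposited values 22 members were higher and 3 lower, with equal counts adjusted over the list alone, against 17 and 7 after quantile normalization. After quantile normalization the differences were 0.66 for Etv4 and -0.62 for Ier3.

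Among the 21 measured RAS genes and close regulators, 6 rose, 2 fell and 13 were not called on both scalings. Rasgrf1 and Sos2, which load RAS with GTP, rose by 0.95 and 0.65, and Rgl1, a RAL exchange factor, by 0.79. Nf1 and Rasa1, which stimulate RAS GTP hydrolysis, rose by 0.49 and 0.43. Rasal2 fell by 0.25 and Map2k1 by 0.23. Nras differed by 0.07 ± 0.09 (adjusted p = 0.569) and Rassf5 by 0.56, or 0.22 and uncalled after quantile normalization. On the deposited values 10 members were higher and 3 lower, both over all genes and adjusted over the list alone, against 6 and 5 after quantile normalization, and the list as a whole was not called (camera adjusted p = 0.733 deposited and 0.497 quantile). Quantile values were 0.55 for Rasgrf1, whose WT mean of 4.82 lies below the dim level, and -0.55 for Rasal2.

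Smooth-muscle contractile genes were lower in KrasD12. Of 23 measured contractile and myofibroblast genes, 11 fell, 2 rose and 10 were not called on both scalings. The actins Actg2 and Acta2 fell by 1.93 ± 0.09 and 1.67 ± 0.09, the actin-binding Cnn1 by 1.65 ± 0.08 and Tagln by 1.49, and smooth-muscle myosin Myh11 by 1.56 ± 0.11. Mylk, Myl9 and the tropomyosin Tpm2 fell by 1.08, 1.05 and 0.93. Synpo2 (1.22) and the collagen-binding integrin gene Itga11 (0.79) rose. The list median was -0.29 deposited and -0.46 after quantile normalization, with camera adjusted p of 6.03e-08 and 0.00266. The call was lost at adjusted p = 0.362 with an estimated correlation (0.689 after quantile normalization). Over all genes 4 members were higher and 13 lower on the deposited values, equal to the counts adjusted over the list alone, against 2 and 12 after quantile normalization.

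**Figure D2:**
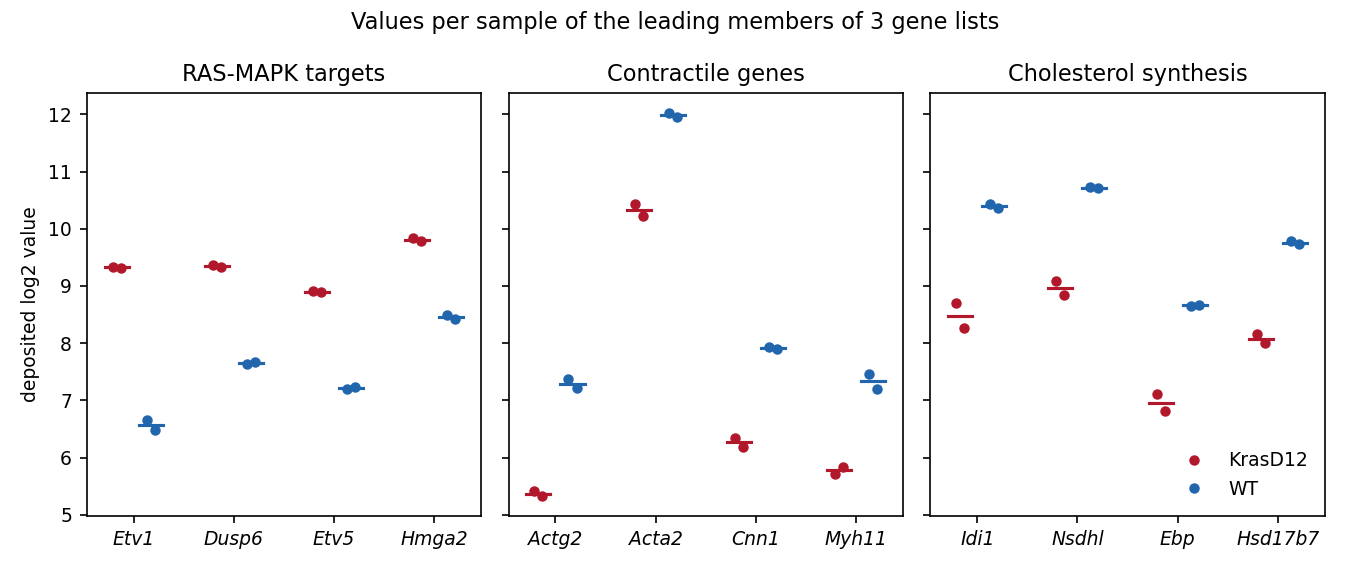
Deposited log2 value (vertical axis) of each sample (points, 2 per group) and the group mean (short lines) for the 4 named members of 3 gene lists, KrasD12 in red and WT in blue. Both KrasD12 samples lie above both WT samples for Etv1, Dusp6, Etv5 and Hmga2 and below them for the contractile and cholesterol synthesis genes.

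Collagens and matrix genes went both ways. Of 25 collagen genes, 5 rose and 5 fell on both scalings: Col12a1 rose by 1.38, Col6a2 by 0.76, Col16a1 by 0.73 and Col6a1 by 0.65, while Col5a2 fell by 1.09 (-1.085), Col1a1, the main fibrillar collagen chain, by 0.60 ± 0.07 and Col8a1 by 0.41. The collagens were not called as a list (camera adjusted p = 0.244 deposited, 0.966 quantile), with 12 higher and 6 lower on the deposited values over all genes and adjusted over the list alone, against 5 and 7 after quantile normalization. Of 37 matrix glycoproteins, proteoglycans and crosslinkers, 8 rose and 11 fell. Ltbp2 and the basement membrane protein Nid2 fell by 2.34 and 2.14 (-2.135), Postn by 1.22, Ogn by 1.21 and the crosslinking enzyme Lox by 0.96, whereas Mfap4 and Tnc rose by 1.57 and 1.28 and fibronectin (Fn1) by 0.44. Camera called this list lower on the deposited values (adjusted p = 0.00932, against 0.829 after quantile normalization and adjusted p = 0.56 with an estimated correlation), although its median was 0.05, and 15 members were higher and 12 lower over all genes and adjusted over the list alone, against 9 and 11 after quantile normalization. Of 26 matrix proteases and inhibitors, 9 rose and 7 fell. The collagenase Mmp13 fell by 2.25 (-2.245), Adam12 by 1.83, Adamts9 by 1.17 and the inhibitor Timp1 by 1.13, and Mmp23 and the gelatinase Mmp2 rose by 1.11 and 1.07. The protease list, with a median of 0.11, was also called lower on the deposited values (adjusted p = 0.0261; 0.966 quantile; adjusted p = 0.522 with an estimated correlation), with 13 members higher and 9 lower, or 13 and 10 adjusted over the list alone, against 9 and 8 after quantile normalization.

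Sterol synthesis was the list with the widest shift. Of 26 measured genes of cholesterol and fatty acid synthesis, 25 fell and 0 rose on both scalings, and Srebf1 stood at 0.28. Idi1 fell by 1.93 ± 0.15, Nsdhl by 1.76 ± 0.10, Ebp by 1.70 ± 0.11 and Hsd17b7 by 1.68 ± 0.08, all enzymes between mevalonate and cholesterol. Cyp51, Sqle, Mvd and Hmgcs1 fell by 1.44, 1.43, 1.40 and 1.24, the fatty acid enzymes Acly, Fasn and Scd1 by 0.85, 0.77 and 0.61, and Srebf2, the transcription factor of sterol synthesis, by 0.50. The list median was -0.97 on the deposited values and -1.07 after quantile normalization, and 0 of 10000 matched random lists reached it. Camera gave adjusted p = 2.48e-22 deposited and 1.3e-11 quantile, and adjusted p = 0.48 with an estimated correlation (0.689 quantile). Deposited calls were 1 higher and 25 lower over all genes and adjusted over the list alone, against 0 and 25 after quantile normalization.

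Genes of the unfolded protein and integrated stress response were lower, 16 of 30 falling and 1 rising on both scalings. The serine synthesis enzyme Psat1 fell by 1.40 ± 0.07, the secreted ER stress protein Manf by 1.36 ± 0.07, the disulphide isomerase Pdia6 by 0.91 and the ER chaperone Hspa5 by 0.85, and Sesn2 rose by 0.63. The list median was -0.41 deposited and -0.47 quantile (camera adjusted p = 7.48e-09 and 0.000563), and the call was lost at adjusted p = 0.362 with an estimated correlation (0.689 quantile). Deposited counts were 4 higher and 18 lower over all genes and adjusted over the list alone, against 1 and 17 after quantile normalization. Of 28 respiratory chain genes 11 fell, among them Uqcrb (-0.84), Ndufa4 (-0.64) and Ndufa1 (-0.52), and 1, Cox5a (0.49), rose. Camera called the respiratory chain lower on both scalings (adjusted p = 2.02e-06 and 0.0145; adjusted p = 0.362 with an estimated correlation, 0.689 quantile), with medians of -0.15 (-0.145) and -0.22 and deposited counts of 3 higher and 11 lower, unaltered when adjusted over the list alone, against 1 and 12 after quantile normalization.

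Of 22 glycolysis genes measured, 9 fell, 2 rose and 11 were not called on both scalings, with falls of 1.25 for Pfkfb3, 0.83 for Ldha, 0.56 for Tpi1 and 0.55 for Pgk1, and a rise of 1.26 for the glucose transporter gene Slc2a3. As a list, glycolysis was called on the deposited values only (camera adjusted p = 0.000128, against 0.0595 quantile and adjusted p = 0.362 with an estimated correlation), with 5 members higher and 9 lower over all genes and adjusted over the list alone, against 2 and 10 after quantile normalization. Of 28 NRF2 and oxidative stress genes 12 fell and 5 rose. Txn1 and Sod2 fell by 1.12 and 1.10 and the antioxidant enzyme genes Aldh3a1 and Gsta4 rose by 0.83 and 0.81. That list was called on the deposited values (adjusted p = 8.86e-05) and not after quantile normalization (0.079), nor at adjusted p = 0.362 with an estimated correlation, with 5 higher and 12 lower over all genes and adjusted over the list alone, against 5 and 15 after quantile normalization. Of 20 hypoxia response genes 6 fell and 4 rose, with Plod1 up by 1.29, P4ha2 down by 0.90, and Ddit4 and Mxi1 up by 0.64 and 0.63. The hypoxia list, at a median of 0.02, was called lower on the deposited values (adjusted p = 0.0115; 0.286 quantile; adjusted p = 0.522 with an estimated correlation; 0.0538 without WT B), with 4 higher and 7 lower over all genes and adjusted over the list alone, against 4 and 9 after quantile normalization. Of 24 ribosomal protein genes 2 fell, Rpl7 by 0.37 and Rpl38 by 0.33 (-0.325), and 0 rose, while Rps18 (-0.33) and Rpsa (-0.27) were called on the deposited values only. The ribosomal list was called lower on the deposited values (adjusted p = 8.95e-05; adjusted p = 0.48 with an estimated correlation) and its direction turned after quantile normalization (0.966), with 0 higher and 7 lower over all genes and 0 and 3 adjusted over the list alone, against 4 and 3 after quantile normalization. On the quantile scale the sizes were 0.43 for Aldh3a1, 0.41 for Mxi1 and -0.24 for Rpl7.

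Interferon-stimulated genes were lower in KrasD12, with 15 of 32 falling and 1, Psmb9 (0.64), rising. Rtp4 fell by 1.16 ± 0.23, Bst2, which tethers virus particles, by 0.99 ± 0.15, the RNA sensor gene Ifih1 by 0.91 ± 0.13 and Mx1 by 0.88, the last with means below the dim level in both groups. Rtp4 lost its call with the replicate letter as a block (adjusted p = 0.0582). Iigp1 fell by 0.89 ± 0.29, with -0.49 (-0.485) when WT A was left out and -1.29 (-1.285) when WT B was left out, and also lost its call with that block (adjusted p = 0.159). The list median was -0.37 deposited and -0.49 quantile (camera adjusted p = 8.36e-06 and 0.00456), and the call was lost at adjusted p = 0.56 with an estimated correlation (0.766 quantile). Limma's fry, which tests a list without comparing it to other genes, did not call a shared direction (fry adjusted p = 0.365 deposited and 0.15 quantile). Deposited counts were 5 higher and 15 lower, or 5 and 17 adjusted over the list alone, against 1 and 18 after quantile normalization. The spread between A and B was wide for Rtp4 in KrasD12 (SD 0.474) and for Iigp1 in WT (SD 0.566). Psmb9 stood at 0.39 after quantile normalization.

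Cytokine and chemokine genes moved in both directions, 7 rising and 10 falling among 35. The eosinophil chemokine gene Ccl11 rose by 2.35 (2.345) and Il11 by 1.09, while the neutrophil chemokine gene Cxcl5 fell by 2.31 (-2.305), Ccl8 by 1.12, and Ccl2 by 1.02. Il6 (-0.53) passed on both scalings with means below the dim level in both groups. The list was not called (camera adjusted p = 0.0831 deposited, 0.286 quantile), with 16 higher and 11 lower on the deposited values over all genes and adjusted over the list alone, against 7 and 13 after quantile normalization. With the filter on dim genes, which kept 19 of its 35 members, camera called it lower (adjusted p = 0.012). Of 32 growth factors and receptors 8 rose and 9 fell. Igf1 fell by 1.99 (-1.985), the lymphangiogenic factor gene Vegfd by 1.22, Fgf18 by 1.13 and Fgf2 by 1.05, while Hgf rose by 1.30 and Igf1r by 0.85. Pdgfra, with a mean between 11 and 12, stood at 0.26 ± 0.07, against a median of -0.15 (-0.145) for genes in that range. Its difference was 0.46 after quantile normalization, but -0.09 (-0.085, limma adjusted p = 0.354) after median centring. This list, at a median of 0.08, was called lower on the deposited values (adjusted p = 0.00932; 0.289 quantile; adjusted p = 0.522 with an estimated correlation), with 9 higher and 10 lower over all genes and adjusted over the list alone, against 8 and 12 after quantile normalization. Sizes that shifted over 1.5 times with quantile normalization were 0.70 for Il11 and -0.85 for Il6.

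Of 27 TGF-beta pathway and target genes 13 rose and 5 fell. The inhibitory helix-loop-helix genes Id3, Id1 and Id2 rose by 1.62, 1.30 and 0.69, and Tgfbi by 1.30, while Ccn1, the antagonist gene Grem1 and Bmp4 fell by 1.19, 0.83 and 0.61. The TGF-beta list was not called (camera adjusted p = 0.923 deposited, 0.289 quantile), with 17 higher and 5 lower over all genes and adjusted over the list alone, against 13 and 7 after quantile normalization. Among 33 WNT pathway genes 9 rose and 8 fell. Dkk2 rose, as did Sfrp2 (1.10), Dkk3 (1.05), the ligand gene Wnt5a (1.04) and the feedback gene Axin2 (0.94), whereas Ccn5 (-2.65), the WNT-enhancing Rspo3 (-1.87) and Sfrp1 (-1.70) fell. The WNT list was not called (camera adjusted p = 0.425 and 0.722), with 14 higher and 8 lower, or 15 and 8 adjusted over the list alone, against 9 and 11 after quantile normalization. Of 24 YAP and TEAD targets 5 rose and 9 fell. Ankrd1 rose by 2.22 (2.215), while F3, the tissue factor gene, fell by 1.39, Ccn1 by 1.19, Wwc1 by 0.99 (-0.985) and Ccn2 by 0.33. The YAP list, at a median of 0.02, was called lower on the deposited values (adjusted p = 0.0033; 0.373 quantile; adjusted p = 0.366 with an estimated correlation), with 7 higher and 9 lower over all genes and adjusted over the list alone, against 5 and 10 after quantile normalization. Axin2 stood at 0.57 after quantile normalization.

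Among 39 transcription factors of lung mesenchyme and positional genes 18 rose, 3 fell and 18 were not called on both scalings. Hhip, a hedgehog-binding target gene, rose by 2.71 ± 0.16, Gli2 by 1.78 ± 0.07, Gli3 by 1.07 and the receptor gene Ptch1 by 0.94, while Gli1 (0.41, or 0.06 quantile) was called on the deposited values only. Snai2 and Snai1 rose by 1.20 and 0.89, and Hoxb5, Hoxb3 and Hoxb4 by 0.91, 0.77 and 0.69. Tcf21, a factor of lipofibroblast lineage, fell by 2.03 ± 0.14, Tbx4 by 0.79 and Twist1 by 0.33. Camera gave adjusted p = 0.189 on the deposited values and 0.0145 after quantile normalization, with medians of 0.51 and 0.22, and adjusted p = 0.689 with an estimated correlation. Deposited counts were 27 higher and 3 lower over all genes and adjusted over the list alone, against 18 and 7 after quantile normalization.

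Of 33 S-phase genes 3 rose and 9 fell, with falls of 1.12 for the ribonucleotide reductase gene Rrm2, 0.81 for Uhrf1, 0.69 for Prim1 and 0.63 for the replication clamp gene Pcna, and a rise of 0.62 for Mcm2. The S-phase list, at a median of 0.09 deposited and -0.21 quantile, was not called on these scalings (camera adjusted p = 0.0636 and 0.059) but was after cyclic loess (0.0447), with 12 higher and 9 lower, or 13 and 9 adjusted over the list alone, against 3 and 14 after quantile normalization. Among 35 genes of G2 and mitosis 3 rose, Cdc25b (0.76), Ube2c (0.75) and Cdc20 (0.69), and 6 fell, including Cenpf (-0.66) and Kif4 (-0.64), while Cenpe (0.73) was called on the deposited values only. Camera did not call the mitotic list (adjusted p = 0.209 and 0.157), with 13 higher and 6 lower, or 12 and 5 adjusted over the list alone, against 3 and 14 after quantile normalization. Of 30 cell cycle inhibitors, p53 targets and senescence genes 9 rose and 7 fell: Igfbp5, Gadd45g and Gadd45b fell by 1.94, 1.80 and 0.98, and Plk3, Cdkn1b, Cdkn1c and Cdkn2b rose by 0.81, 0.70, 0.68 and 0.61. Cdkn2a, which encodes the inhibitors p16 and p19, stood at 0.26 ± 0.09 and was not called (adjusted p = 0.0587), although it passed with the replicate letter as a block (0.0431), among genes above the dim level (0.0448) and with an intensity trend in eBayes (0.0189). The list was not called (adjusted p = 0.108 and 0.829), with 12 higher and 8 lower over all genes and adjusted over the list alone, against 9 and 8 after quantile normalization. Of 38 DNA damage and repair genes 8 rose and 2 fell. Ddb2, Chek2, Atm and Rad52 rose by 0.95, 0.70, 0.69 and 0.69, and Lig4 and Polh fell by 0.40 and 0.39. The repair list was not called (adjusted p = 0.454 and 0.966), with 22 higher and 2 lower, or 23 and 2 adjusted over the list alone, against 8 and 9 after quantile normalization. With quantile normalization the values became 0.50 for Cdc25b, 0.41 for Ube2c, 0.38 for Cdc20, -1.04 for Cenpf, -1.02 for Kif4 and 0.52 for Plk3. After quantile normalization the differences were 0.44 for Chek2, -0.61 for Lig4 and -0.65 for Polh.

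Markers of lung fibroblast subtypes and neighbouring cell types gave mixed results, and none of these lists was called by camera. Of 23 alveolar and lipid-storing fibroblast markers 6 rose and 6 fell, led by Adh1 (1.79), Npnt (-1.59) and Gpc3 (-1.23); the list had adjusted p = 0.454 deposited and 0.734 quantile, with 10 higher and 6 lower over all genes and adjusted over the list alone, against 6 and 9 after quantile normalization. Of 18 adventitial fibroblast markers 3 rose, Ccl11, Sfrp2 and Cd34 (0.55), and 3 fell, while Il33 (0.60) was called on the deposited values only. The adventitial list had adjusted p = 0.439 and 0.966, with 9 higher and 4 lower over all genes and adjusted over the list alone, against 3 and 4 after quantile normalization. Of 20 smooth muscle and pericyte markers 4 rose, including Hhip, Trpc6 (1.17) and Cspg4 (0.76), and 6 fell, which were Actg2, Acta2, Cnn1, Myh11, Postn and Pdgfrb (-0.50). The smooth muscle list had adjusted p = 0.266 and 0.497, with 10 higher and 6 lower over all genes and adjusted over the list alone, against 4 and 7 after quantile normalization. Quantile values were 0.27 for Cd34, 0.76 for Trpc6 and 0.39 for Cspg4.

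Lists of markers of cells other than fibroblasts were not called on the deposited or quantile values either, although camera called leukocyte markers after median centring (adjusted p = 0.0318). Of 28 lung epithelial markers 15 had a mean above the dim level, 5 rose and 0 fell. Scgb3a2, Sftpc and Grhl2 rose by 1.04, 0.92 and 0.75 with KrasD12 means of 4.15, 5.27 and 4.85, and Sftpb by 0.70 to a mean of 5.95. Scgb3a2 and Grhl2 lay below the dim level in both groups. The epithelial list had a median of 0.44 deposited and 0.07 quantile (adjusted p = 0.101 and 0.497), with 18 higher and 0 lower over all genes and adjusted over the list alone, against 5 and 4 after quantile normalization. Of 16 mesothelial markers, 11 of them above the dim level, Nkain4 (-2.52) and Cpe (-0.40) fell, while Gpm6a (0.89) passed on both scalings with means below the dim level in both groups (4.43 and 3.54), and Upk3b (0.57) and Krt8 (0.49) were called on the deposited values only. The mesothelial list had adjusted p = 0.189 and 0.152, with 4 higher and 2 lower over all genes and adjusted over the list alone, against 1 and 6 after quantile normalization. Of 22 endothelial markers, 9 of them above the dim level, Sox18 (0.66) rose and Eng and Flt1 (-0.51) fell. Prox1 (0.78) passed on both scalings with means below the dim level in both groups (4.66 and 3.88), and Tie1 (0.60) was called on the deposited values only. The endothelial list had adjusted p = 0.503 and 0.51, with 15 higher and 2 lower over all genes and adjusted over the list alone, against 2 and 4 after quantile normalization. Of 30 leukocyte markers, 11 of them above the dim level, 8 rose and 3 fell. C1qa rose by 1.51 to a mean of 6.17 and S100a9 by 0.88 to 5.20, and Lyz2 fell by 1.48 to 4.63. Cd79a (1.02) passed on both scalings with means below the dim level in both groups (4.40 and 3.38). The leukocyte list had adjusted p = 0.116 and 0.497, with 19 higher and 3 lower, or 21 and 3 adjusted over the list alone, against 8 and 5 after quantile normalization. Of 21 markers of neural crest, glia and skeletal muscle, 16 of them above the dim level, 6 rose and 2 fell, with rises of 1.97 for Pax3, 0.89 for Nes, 0.88 for S100b and 0.82 for Chrna1. This list had adjusted p = 0.189 and 0.463, with 15 higher and 2 lower, or 17 and 2 adjusted over the list alone, against 6 and 4 after quantile normalization. On the quantile scale the sizes were 0.71 for Scgb3a2, 0.52 for Sftpc, 0.34 for Grhl2, 0.32 for Sftpb, -0.26 for Cpe, 0.53 for Gpm6a and 0.32 for Sox18. Sizes that shifted over 1.5 times with quantile normalization were -0.82 for Flt1, 0.38 for Prox1, 0.47 for S100a9, 0.66 for Cd79a, 0.47 for S100b and 0.43 for Chrna1.

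Among the fixed names, Vim, the intermediate filament of mesenchymal cells, stood at 12.8 in KrasD12 and 12.9 in WT (difference -0.11 ± 0.07, adjusted p = 0.215). Limma called Vim lower after median centring (-0.45, adjusted p = 0.00337) and with a trend in eBayes (adjusted p = 0.024). After quantile normalization the Vim difference was 0.00 (0.000625) and was not called. Of 10 sex-linked genes 3 rose and 3 fell. The Y-linked Kdm5d and Uty rose by 0.79 (0.785) and 0.55, the X-linked Kdm6a by 0.72, and Eif2s3y (-0.21, adjusted p = 0.0767) and Usp9y (0.43, or 0.11 quantile) were not called on both scalings. Kdm5d, Uty and Eif2s3y had means of 7.24 to 9.02 in both groups, and Xist, which is expressed from the inactive X chromosome, lay below the dim level in both (4.06 and 4.35). The sex-linked list was not called (camera adjusted p = 0.189 and 0.827), with 4 higher and 4 lower over all genes and adjusted over the list alone, against 3 and 4 after quantile normalization. With quantile normalization the values became 0.48 for Kdm6a and -0.68 for Xist.

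**Figure D3:**
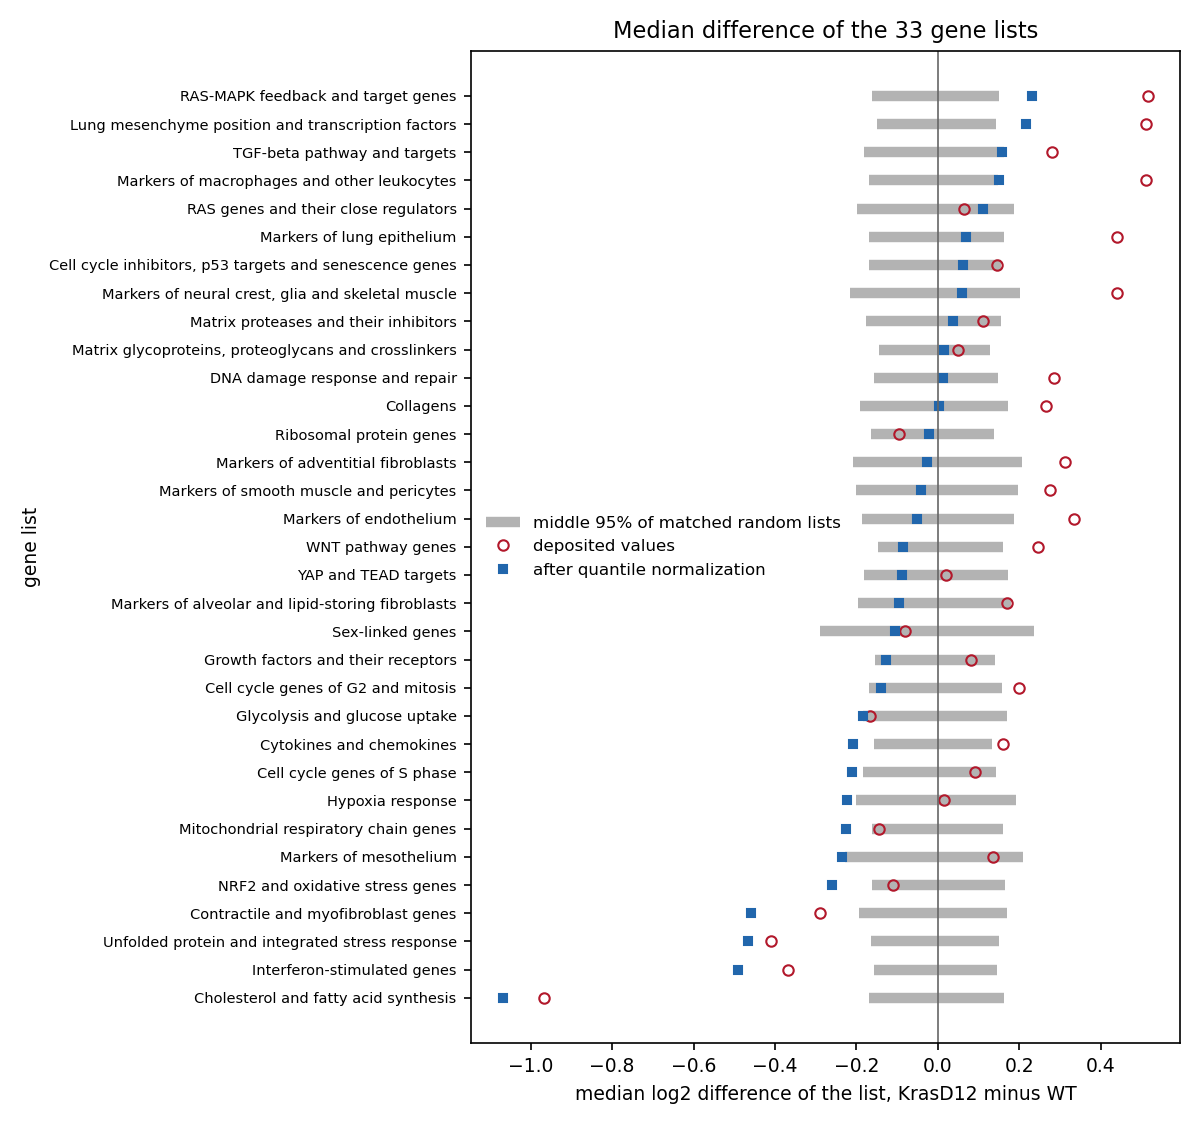
Median log2 difference between KrasD12 and WT (horizontal axis) of each of 33 gene lists (vertical axis) on the deposited values (open circles) and after quantile normalization (squares), with the middle 95% of 10000 random lists matched on mean expression after quantile normalization (grey bars). Cholesterol and fatty acid synthesis lies farthest to the left, at -1.07 after quantile normalization, and the RAS-MAPK targets farthest to the right, at 0.23.

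Camera called 13 of the 33 lists on the deposited values and 7 after quantile normalization. The 5 called lower on both scalings were cholesterol synthesis, the unfolded protein response, contractile genes, interferon-stimulated genes and the respiratory chain. Fry's directional test also called these on both scalings, except the interferon-stimulated genes (fry adjusted p = 0.365 deposited and 0.15 quantile). With an estimated correlation 0 lists were called on either scaling. That setting rests on the 2 residual degrees of freedom, so a list could hardly pass. The cholesterol list, with 25 of 26 members lower, had an unadjusted camera p of 0.116 there on the deposited values. Lists with smaller shifts had lower unadjusted camera p: 0.0283 for the respiratory chain, 0.0398 for NRF2 genes and 0.0454 for contractile genes. All lists share the degrees of freedom, which therefore do not account for this order. On the deposited values the median, the mean and the direction of camera did not share a sign in 18 lists, of which 5 were called; after quantile normalization this held for 7 lists, of which 0 were called. Counts adjusted over the list alone equalled those over all genes in 24 of 33 lists on the deposited values and in 17 after quantile normalization.

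Genes of some chromosomes were shifted together by small amounts. Among genes above the dim level, those of chromosome 4 (871 genes) lay 0.17 (0.165) above the other genes and those of chromosome 7 (1113 genes) 0.07 above. Genes of chromosome 13 lay -0.12 (-0.115), of chromosome 3 -0.10 (-0.095), of chromosome X -0.08 and of chromosome 1 -0.07 (-0.065) from the others. The permutation test gave adjusted p of 5e-04 for chromosomes 3, 4, 7 and 13, where the raw p of 1e-04 is the smallest the permutations can give, and 0.0032 and 0.00633 for chromosomes 1 and X. After quantile normalization the same 6 chromosomes passed, with 0.11 (0.1063) for chromosome 4 and 0.04 for chromosome 7, and so did chromosomes 8 (0.04) and 15 (-0.06). Among all genes, without the filter on dim ones, chromosomes 3, 4, 7 and 13 passed, while chromosomes 1 (adjusted p = 0.0959) and X (0.315) did not.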

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

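The tests of this part were chosen after the data were seen. Rows to which the annotation gives no gene symbol took part in no comparison above, and 241 of them differed at least 2-fold and were called in the same direction on the deposited values and after quantile normalization, 212 higher and 29 lower in KrasD12. Many of them repeat 1 measurement: the 241 rows hold 118 distinct sets of 4 values, 89 higher and 29 lower, and the 3 largest repeated sets, all higher, take up 50, 33 and 23 rows. The largest rise was that of row 10608655, from 5.11 to 8.21 (log2 difference 3.10; 2.83 after quantile normalization), and the largest fall that of row 10588037, from 9.67 to 6.73 (log2 difference -2.94; -3.13 after quantile normalization). What these rows measure stays open here.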

How the results depend on the processing

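Cyclic loess, the requirement of calls on both scalings, and quantile normalization together with an estimated correlation were chosen after the data were seen; the other settings were fixed beforehand. The replicate block left 10260 genes called (8350 higher, 1910 lower), 983 at 2-fold, and all 33 lists on their side of the threshold. Among the named genes it ended the calls of Rtp4 (limma adjusted p 0.0582) and Iigp1 (0.159). It added one for Cdkn2a (0.0431, against 0.0448 with the dim filter and 0.0189 with the trend). The A minus B differences of the groups correlate at r = 0.0132 across genes, so no difference shared by the letters is visible. Whether the letters pair the samples by design is not given. Against 12372 calls (9991 higher, 2381 lower) and 985 at 2-fold (728 and 257), quantile normalization gave 4485 higher and 4861 lower, and 249 and 439 at 2-fold. Median centring gave 3574 and 6657, and 204 and 608. Cyclic loess gave 4533 and 4933, and 244 and 448. Calls on both scalings numbered 6757 (4459 higher) and 501 at 2-fold (246 higher). The move between higher and lower calls follows from the construction of these settings, which take the groups to the same centre or distribution. Without shrinkage 3668 genes were called (2838 higher, 830 lower), limma's treat called 201 (117 and 84), and testing every row, named or not, gave 1765 at 2-fold (1461 higher); the cause of these was not tested beyond the differing statistic and number of rows. With 1 array left out, calls ranged from 0 to 5783 (0 to 4623 higher, 0 to 1160 lower), those at 2-fold from 0 to 967 (0 to 714 higher, 0 to 253 lower), lists from 12 to 13 and chromosomes from 6 to 8, against 4 chromosomes without the dim filter. These fits keep 1 residual degree of freedom and assume that the lone sample varies like the other group; their prior degrees of freedom were 0.954 and 1.13, against 3.36 with all arrays. Of 152 named genes, 9 lost their call after quantile normalization, 10 after cyclic loess and 9 after median centring, and the cause was not tested. Pdgfra turned from 0.26 to -0.09 (-0.085, limma adjusted p 0.354) after median centring. That follows from the setting, which takes the difference of the column medians (6.24 and 6.26 in KrasD12, 5.9 and 5.91 in WT) off every gene. The 13 lists called became 7 after quantile normalization, 8 after cyclic loess, 0 with an estimated correlation on the deposited or the quantile values, and 33 by fry's mixed test, which asks only whether the members of a list change; fry's directional test called 19. The direction of the ribosomal protein list turned after quantile normalization and after cyclic loess, and the cause was not tested. Its median less that of all genes was -0.02 (-0.018) after quantile normalization, with camera pointing up at the preset and the estimated correlation. After cyclic loess that value was 0.01 (0.00991). RAS-MAPK targets passed with quantile normalization, median centring (adjusted p 0.0125), the dim filter (0.0319), the trend (0.0288) and cyclic loess (0.018), lung mesenchyme factors with the first 2 of these and cyclic loess, cytokines with the dim filter (0.012), S-phase genes after cyclic loess (0.0447) and leukocyte markers after median centring (0.0318). A filter on dim genes, eBayes with a trend or robust, the mean of a gene's rows and unadjusted p-values left the total counts within 1.5 times. Robust eBayes, the mean of rows and every row were not run for the lists. Where a group lies below the dim level of 5.15, signal over background limits the size of a difference.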

Other observations

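The tests of this part were chosen after the results were seen, except the one that leaves out each array for the cholesterol genes. 5 gene families that no list above covers as such were looked at, and their members were chosen after values had been seen. Of 4 Aldh1a genes 3 fell, Aldh1a7 by 2.62 ± 0.07, Aldh1a1 by 1.04 ± 0.08 and Aldh1a3 by 0.51 ± 0.07 (-0.90 quantile), and Aldh1a2 stood at 0.02 (0.015, adjusted p = 0.923). Of 9 hedgehog pathway genes 5 rose, Hhip, Gli2, Gli3, Ptch1 and Cdon (0.90, or 0.50 quantile, below the dim level in both groups), while Gli1 stood at 0.41 deposited and 0.06 quantile. Glutamate receptor genes split, 4 of 15 rising, among them the kainate receptors Grik1 (2.90) and Grik2 (2.07, that is 2.065), and 4 falling, among them Grin2a (-1.15). Of 10 EGF-family ligands 1 rose and 3 fell, Btc by 1.06 (-1.055), Ereg by 1.03 (-1.025) and Nrg1 by 1.03, and of 22 protocadherin beta genes 6 rose and 1 fell.

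On the deposited values 80.8% of the called genes were higher in KrasD12. Genes with a mean above 10, 864 of 19938, had a median of -0.10 (-0.095), so the brightest genes did not rise with the rest. Genes in the intervals of lower means had medians of 0.065 to 0.39. The 864 genes therefore cannot decide whether most transcripts rose. Rows of olfactory and vomeronasal receptors, taken as background, shifted by 0.33, and this is consistent with columns of the 2 groups that were scaled apart. How the values were scaled is not given in the sources used here, and a difference in background between the 2 pairs of arrays would leave the same trace.

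The fall of cholesterol synthesis genes was weighed against 3 explanations. A general fall of bright against dim genes would leave the list within matched random lists after quantile normalization, and 0 of 10000 lists of random genes matched on mean expression lay at or below the cholesterol median of -1.07. With each array left out in turn, the median lay between -1.13 and -1.01 (-1.008), so no array by itself accounts for it. A difference between the lines other than the KrasD12 allele stays open, since there was 1 line per genotype. The fall may therefore reflect the allele, another difference between the lines, or culture conditions such as sterol supply or density, and these cannot be told apart here.

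29 genes differed at least 4-fold on both scalings with 1 group below the dim level and the other above it: 17 were on in WT only, such as Ifi202b (3.48 and 3.68 in KrasD12, 7.78 and 7.65 in WT), Gbp2b (-2.84), Casp1 (-2.72) and Ces2g (-2.64), and 12 in KrasD12 only, such as Trim12a and Mstn (2.49). Grpr (5.20 and 5.09 in WT) and Cbln2 (5.11 on average in WT) lie at the edge of that level. A candidate explanation is that the 2 lines differ in mouse strain background as well as in genotype. Across the chromosomes, 125 of 498 2-fold genes had a 2-fold gene of another family among the 5 nearest measured genes on each side, against a median of 116 and a middle 95% of 93 to 140 for positions permuted within strata of expression (permutation p = 0.229). Whether strain background contributes cannot be told apart from other differences between the lines by this count of 125. A first version of the test, on the 29 genes alone, decides nothing: 0 had another of the 29 so near, and permuted positions also gave a median of 0.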
